A study of Mus musculus with 6 samples.

How the data were processed

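The samples were RNA preparations from mouse hippocampus hybridised to 6 Affymetrix whole-genome mouse arrays, a 1-colour expression array on which a gene is read by one or more probe sets. Per the labels, 3 arrays held RNA from beads carrying anti-myc antibody against transgenic HuD, 2 held RNA from beads with non-immune IgG, and 1 held the total input RNA. The deposited values were intensities on a linear scale, 1 signal per probe set. The mean of the signals without the lowest and highest 2% lay between 149.94 and 149.95 on all arrays, so the authors had already scaled each array to a common level. The software and the method behind the signals were not given in the sources used here. The table held no detection calls, so no probe set could be called absent.

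Of the 45101 probe sets, 64 were array controls and were left out of the tests. A platform annotation paired 34958 probe sets with 1 gene symbol, 932 with several and 9160 with none, and only those with 1 symbol were named. Entrez identifiers of 34754 of them were found in a RefSeq gene table of the GRCm38.p6 assembly, and 0 symbols needed an update. That table served for names only, and no coordinates were used, because no genome build was given for the array. Each of the 18193 genes was represented by the probe set with the highest mean over all 6 arrays, a choice that favours probe sets bright in any group. The 9097 genes in the upper part of the distribution of mean log2 values, split at the median, were tested.

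Signals were transformed as log2(signal + 32), so fold changes are on that scale and understate the change of dim genes. A linear model with 1 mean per group was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3, using eBayes with a mean-variance trend. The model had 3 residual degrees of freedom and the prior added 8.4. Errors printed after ± are standard errors of the log2 difference unless SD is named, and adjusted p-values are limma's, adjusted by Benjamini-Hochberg over the tested genes with a threshold of 0.05. The number of arrays limits the precision. The input group had 1 array, which was assumed to vary like the pulldown arrays. Each gene had 1 variance for all groups, although the IgG arrays differed more than the HuD arrays did. The SD of log2 differences across genes was 0.616 for the IgG pair and 0.314 to 0.457 for HuD pairs. Standard errors may thus understate the IgG spread for HuD against IgG, and for HuD against input they depend on it. The labels do not say that the arrays came from separate animals or preparations, so p-values measure only the spread between these arrays, which may be technical. Replicate numbers follow the order of deposit and only name the arrays.

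The comparisons, their tests, 18 gene lists and the rule for the genes named in the text were fixed before the data were examined. That rule takes Elavl4 first. For HuD against IgG it takes the 14 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap. For HuD against input it takes 10 and 10, and for IgG against input 6 and 6, filled up by the lowest unadjusted p where fewer passed. It adds up to 4 members of each list with the largest absolute difference between HuD and IgG, and every member of the list of neuronal ELAV targets. Further list members are quoted with their values where they show how a list or a gene family divides. Clone-type symbols were counted and not named. Lists were tested with limma's camera at a preset correlation of 0.01, on 17 lists with at least 3 tested genes. The list of mitochondrially encoded genes had 0 members on this array's annotation and gave no result. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. The list of neuronal ELAV targets was written from general knowledge, which can include reports made from these same arrays, so it is not independent evidence of its direction.

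The steps were tested on 20 simulated data sets of 9097 genes with this design for the HuD to IgG comparison. With 200 changed genes, 21.1% of those changed 2-fold, 95.6% of those changed 4-fold and 99.7% of those changed 8-fold were recovered, and 5.93% of the calls were false. With 4500 genes changed 2-fold, 79.3% were recovered and 2.52% of calls were false. With 200 genes changed only 2-fold or 1.5-fold, 0% of either were recovered, and 1 of the 2 calls made over all sets was false, so this design does not find a few small changes. Earlier versions of this simulation used only those small changes, at first with another draw of the variances, and were to recover over 50% of the 2-fold changes, which they did not. The larger changes, the draw of variances from the fitted prior and the setting with many changed genes, to which the mark of 50% was then moved, were adopted after that. A list of 30 genes shifted by 0.5 on the log2 scale was called in 20 of 20 sets, and 0 of 340 unchanged lists were called. The simulated genes varied independently of each other, so these counts cannot show how the list test behaves where genes vary together. In the data the estimated correlation between genes was 0.548 for the list of cytosolic ribosomal proteins. It was 0.512 for that of nuclear-encoded oxidative phosphorylation.

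The alternatives tried were quantile, median and 75th percentile scaling, pseudocounts of 1 and 100, no filter and a stricter filter, every probe set on its own, the mean of a gene's probe sets, eBayes without a trend, the suffix of the sample titles as a block, pairs of like-numbered arrays as a block, the 5 pulldown arrays alone, each array left out in turn, and for lists an estimated correlation and limma's fry. Scaling to the 75th percentile for the lists, and a scan of gene families by the first 3 letters of their symbols, were added after the data were seen. Leaving out either IgG array leaves 1 array in that group, and the spread is then estimated from the HuD arrays alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.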

Results

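The data comprised probe set signals from 6 arrays of mouse hippocampal RNA. HuD, the product of Elavl4, is a neuronal member of the ELAV family of RNA-binding proteins, which bind AU- and U-rich stretches in the 3′ untranslated regions of mRNAs. Mice carrying a myc-tagged HuD transgene allow the protein and its bound RNA to be recovered with an anti-myc antibody. The groups were 3 HuD pulldowns, 2 pulldowns with non-immune IgG as the background control, and 1 sample of total input RNA. Across the 9097 tested genes the 3 HuD arrays resembled each other, with Pearson correlations across genes between 0.965 and 0.984 and between 39 and 322 genes differing at least 2-fold in a pair. Genes are not independent replicates, and these correlations describe the arrays only. The 2 IgG arrays differed at least 2-fold in 945 genes, and IgG arrays differed from the input in 764 and 526 genes. HuD arrays differed from IgG arrays in 3155 to 3864 genes and from the input in 3359 to 3706 genes.

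The comparison of HuD with IgG pulldowns asked which RNAs made up a larger share of the signal with HuD than in the background of the beads. Each array was scaled to a common level, so higher and lower are relative to the other RNAs of an array. A gene called lower need not have been recovered less with HuD in total. Elavl4 RNA itself had a signal of 1997.7 ± 302.8 (SD, n = 3) in the HuD pulldowns, 704.0 ± 87.5 (SD, n = 2) in the IgG pulldowns and 597.3 in the input, a 2.75-fold difference between the pulldowns (log2 fold change 1.46 ± 0.25, adjusted p = 0.00111). All 3 of its probe sets were higher in the HuD pulldowns, with log2 fold changes of 2.13, 1.23 and 1.46. Whether these probe sets read the transgene's RNA is not known here. The highest-ranked rises included Klhl15, an adaptor of Cullin-3 ubiquitin ligases, which was 8.95-fold higher (log2 fold change 3.16 ± 0.26), and Tram1, a protein of the endoplasmic reticulum translocation site, which was 8.86-fold higher (3.15 ± 0.27). Elavl1, which encodes the widely expressed ELAV protein HuR, was 8.33-fold higher (3.06 ± 0.38).

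Of the other leading rises, the F-box gene Fbxo3 was 8.55-fold higher, the sterol synthesis gene Hsd17b7 8.50-fold, Shoc2, a scaffold of Ras signalling, 8.36-fold and Vstm2a 8.13-fold. Ppp6c, the catalytic subunit of protein phosphatase 6, rose 8.06-fold, the noncoding RNA Kantr 8.05-fold, the vesicle fusion gene Sec22b 7.85-fold and the death receptor gene Tnfrsf21 7.68-fold. Nfyb, a subunit of the CCAAT-binding factor, rose 7.45-fold, Txlng 7.42-fold and the claudin gene Cldn34c1 by 2.89 on the log2 scale. The adjusted p of these 14 genes, Klhl15, Tram1 and Elavl1 included, was at most 0.000353. With probe sets averaged most of these rises were smaller and all still past the threshold, for example 1.51 for Klhl15, 1.40 for Fbxo3 and 1.29 for Hsd17b7. Another probe set had a log2 fold change of −0.02 for Txlng, 0.50 for Sec22b, 0.61 for Shoc2, 0.69 for Fbxo3 and 0.69 for Kantr, none past the threshold, and one of the 4 probe sets of Kantr was lower in the HuD pulldowns (−1.20).

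The largest falls were led by Rpl41, a protein of the large ribosomal subunit, which was 7.58-fold lower in the HuD than in the IgG pulldowns (log2 fold change −2.92 ± 0.34), and Psmc4, an ATPase of the proteasome, which was 6.30-fold lower (−2.66 ± 0.42). Dnajc17 was 5.76-fold lower, the splicing factor gene Srrm2 5.24-fold, the translation initiation factor gene Eif3c 5.18-fold and Drosha, the nuclease of microRNA processing, 5.17-fold. Sgf29 was 5.01-fold lower, the Wnt pathway gene Dvl1 4.99-fold, the kinase gene Irak1 4.87-fold and the formin gene Inf2 4.85-fold. The adjusted p of these 10 genes was at most 0.000956. A fall against IgG can also come from signal gained on the IgG arrays. For Srrm2 the IgG signals were 4682.2 and 1898.8, against 684.6 in the input and a HuD mean of 545.5, so its fall rests mainly on the IgG arrays. Another probe set did not pass the threshold for Srrm2 (−0.39), Drosha (−1.06) and Irak1 (−0.48), and one of the 3 probe sets of Rpl41, all called lower, was at −0.775.

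**Figure D1:**
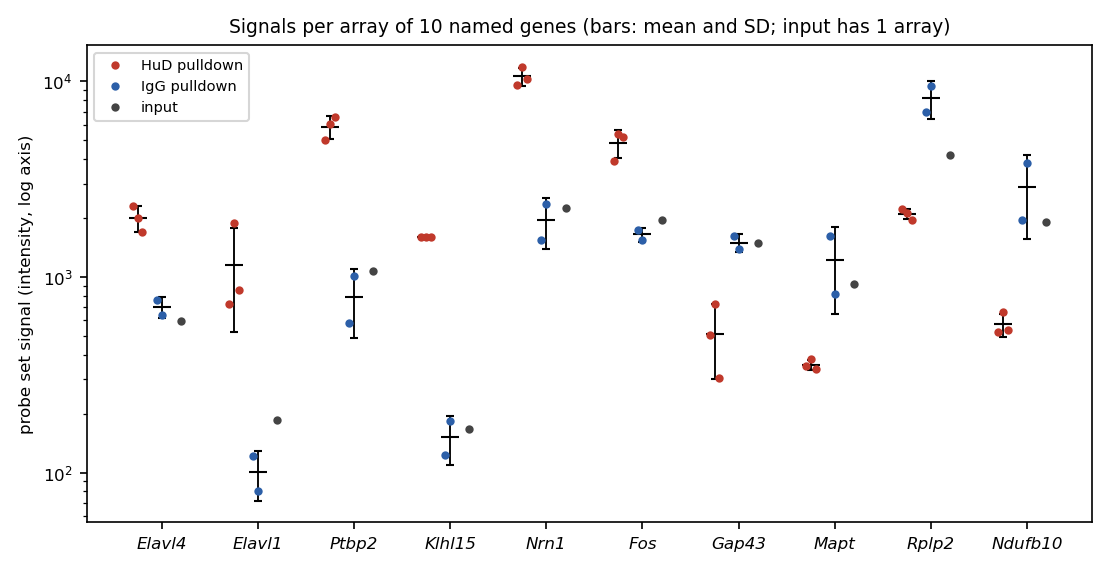
Probe set signals (intensity, log axis) of 10 named genes on the 3 HuD, 2 IgG and 1 input arrays, with bars for the mean and SD of the HuD and IgG groups. Elavl4 lies between 1688.9 and 2294.1 on the HuD arrays and at 642.1 and 765.9 on the IgG arrays, while Gap43 lies between 305.1 and 727.7 on the HuD arrays and at 1386.7 and 1612.2 on the IgG arrays.

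Messenger RNAs of other RNA-binding proteins were mostly higher in the HuD pulldowns. Of 37 tested members 24 rose, 2 fell and 11 did not pass the threshold, and adjusted over the list alone 25 rose and 2 fell. The list's median log2 fold change was 1.15, which is 1.43 above that of all genes (camera, adjusted p = 1.65e-07). With an estimated correlation, 0.047 for this list, its adjusted p was 0.191. Next to Elavl1 the largest rises were those of the splicing repressor Ptbp2 (2.88 ± 0.28), Tial1 (2.87 ± 0.29) and the KH-type splicing regulator Khsrp (2.03 ± 0.38). Fmr1, the gene of fragile X syndrome, rose by 1.68 on the log2 scale, all of Cpeb1, Cpeb2, Cpeb3 and Cpeb4 rose (0.85, 1.58, 1.81 and 1.64), and Hnrnpa1 fell by 1.17. Among the ELAV paralogs Elavl2 rose (1.54) and Elavl3 did not pass the threshold (−0.52). Related sequences can bind the same probes, so values of the ELAV paralogs are uncertain, and 4 of the other probe sets of Elavl1 had log2 fold changes of 2.01, 1.83, 1.52 and 0.59. For Tial1, 3 of the other 4 probe sets were not past the threshold, at 0.03, −0.07 and −0.37, and the remaining one rose by 1.07. Another probe set of Khsrp, at 0.525, did not pass.

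Of 21 tested neuronal ELAV targets, genes reported to be bound or regulated by neuronal ELAV proteins, 12 rose, 3 fell and 6 did not pass. Adjusted over the list alone 13 rose and 4 fell. The median log2 fold change was 0.88 (camera, adjusted p = 0.00145, and adjusted p = 0.191 with an estimated correlation). The list is not independent evidence of its direction, since its members can come from reports on these arrays. The neurite growth gene Nrn1 rose 5.45-fold (2.45 ± 0.24), the chromatin organiser Satb1 3.95-fold (1.98 ± 0.25), the neurotrophin Bdnf 3.01-fold (1.59 ± 0.26) and the immediate early gene Fos 2.87-fold (1.52 ± 0.24). Smaller rises were those of Homer1 (1.43), Mycn (1.37), Cdkn1b (1.33), Cdkn1a (1.33), Atg5 (1.24), Msi1 (1.17), Marcks (0.88) and Nova1 (0.88). The microtubule-associated protein gene Mapt fell 3.06-fold (−1.62 ± 0.31), the growth cone gene Gap43 fell 2.95-fold (−1.56 ± 0.33) and Ache fell 1.79-fold (−0.84 ± 0.30). Camk2a (−0.97 ± 0.41), Bace1 (0.58), Vegfa (0.52), Cplx2 (0.36), App (0.15) and Kcna1 (0.03) did not pass.

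Several of these calls changed with the setting or with 1 array left out. Ache was not past the threshold under any of the other 3 scalings of the arrays (−0.52 with 75th percentile centring), nor without HuD array 1 (−0.585) or IgG array 1 (−0.56). Nova1 was not past it without HuD array 1 (0.73) or IgG array 2 (0.56), nor Msi1 without HuD array 2 (0.90) or IgG array 2 (1.025). Mycn was at 0.88 without IgG array 1 and still passed. Bace1 and Vegfa passed with 75th percentile centring (0.90 and 0.84), Camk2a with quantile normalization (−1.14) and without HuD array 3 (−1.25), and Cplx2 without IgG array 1 (0.85). Homer1 and Mapt were not past it when the probe sets of a gene were averaged (0.43 and −0.76), and none of the other 4 probe sets of Homer1 or the other 3 of Mapt passed. Other probe sets of Bdnf (0.565), Cdkn1a (0.42), Atg5 (0.57 and 0.23) and Marcks (0.375) did not pass either, while 2 others of Camk2a were called lower (−1.445 and −0.97).

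Of 11 tested classical AU-rich mRNAs 8 rose, 1 fell and 2 did not pass, and the counts adjusted over the list alone were the same. The median log2 fold change was 1.01 (camera, adjusted p = 0.00145, and adjusted p = 0.191 with an estimated correlation, −0.066 for this list and so also below the preset). The hypoxia factor Hif1a rose 4.24-fold (2.08 ± 0.24), the cyclin gene Ccnd1 2.99-fold (1.58 ± 0.38) and the phosphatase gene Dusp1 2.57-fold (1.36 ± 0.23), while Ier3 fell (−0.76). Without IgG array 2 the rise of Ccnd1 was 0.90 and still passed, and its other probe sets, at 0.52 and 0.86, did not pass. Fos, Cdkn1a and Vegfa stand in this list and in that of ELAV targets. Of 14 immediate early genes 5 rose and 3 fell, also when adjusted over the list alone (median 0.65, camera, adjusted p = 0.104). Nr4a2 rose (1.36 ± 0.25, with other probe sets at 0.44 and 0.10 that did not pass), while Nr4a1 (−1.01), Arc (−0.95) and Npas4 (−1.04 ± 0.38) fell. Npas4 did not pass under the other 3 scalings (−0.72 with 75th percentile centring), with the title suffix as a block (−0.99), or without HuD array 1 (−0.96), HuD array 3 (−0.76) or IgG array 1 (−0.57).

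Genes of the ribosome and of the respiratory chain were lower in the HuD pulldowns. Of 44 cytosolic ribosomal protein genes 0 rose, 34 fell and 10 did not pass, and adjusted over the list alone 35 fell. Their median log2 fold change was −1.37, which is −1.08 relative to all genes (camera, adjusted p = 3.43e-07, and adjusted p = 0.461 with an estimated correlation). Next to Rpl41, Rps15 fell 4.04-fold (−2.01 ± 0.30), Rplp2 3.82-fold (−1.93 ± 0.23) and Rps10 3.71-fold (−1.89 ± 0.36). Of 66 nuclear-encoded genes of oxidative phosphorylation 0 rose and 60 fell, and adjusted over the list alone 61 fell (median −1.30, camera, adjusted p = 1.24e-09, and adjusted p = 0.461 with an estimated correlation). Ndufb10 fell 4.60-fold (−2.20 ± 0.31), Uqcrh 4.04-fold (−2.02 ± 0.30), the ATP synthase gene Atp5e 3.92-fold (−1.97 ± 0.33) and Atp5md 3.81-fold (−1.93 ± 0.56). Without IgG array 2 the fall of Rps10 was −1.20 and still passed. The Atp5md call was lost without HuD array 2 (−1.70) and without IgG array 2, where its difference was −0.66. Centred on the 75th percentile, 24 ribosomal and 34 oxidative phosphorylation genes fell and 0 rose, with medians of −1.05 and −0.99. Within the title suffix le1 the medians of the ribosomal and oxidative phosphorylation lists were −0.88 and −0.81, and within the suffix e1_le1 they were −1.70 and −1.68.

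Neuronal lists moved in both directions and did not pass the list test. Of 30 genes of axon growth and the neuronal cytoskeleton 6 rose and 15 fell, and adjusted over the list alone 6 rose and 16 fell (median −0.64, camera, adjusted p = 0.433). Nrn1 and the adhesion molecule Ncam1 (2.13 ± 0.25) rose, while Mapt, Gap43, the tubulin gene Tubb2a (−1.61 ± 0.22) and the neurofilament genes Nefl (−1.12), Nefm (−1.61) and Nefh (−1.22) fell. With its probe sets averaged, Ncam1 was at 0.28 and did not pass, and a second probe set of Tubb2a was at −0.665 and did not pass. Of 24 synaptic vesicle genes 5 rose and 8 fell, also over the list alone (median −0.25, adjusted p = 0.991). Vamp2 rose (1.62 ± 0.22), with a second probe set at 0.29 that did not pass, and Syp (−1.86 ± 0.43), Amph (−1.65 ± 0.27) and Dnm1 (−1.40 ± 0.24) fell. With probe sets averaged, Syp was at −0.78 and did not pass, and without IgG array 1 it was at −0.93 and passed. A second probe set of Dnm1, at −0.59, did not pass.

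Of 23 postsynaptic genes of glutamate signalling 6 rose and 4 fell, also over the list alone (median −0.13, with camera's direction upward, adjusted p = 0.433). The metabotropic receptor gene Grm5 (1.66 ± 0.25) and Homer1 rose, and Dlgap2 (−1.88 ± 0.45) and Shank3 (−1.43 ± 0.29) fell. For Dlgap2 the IgG signals were 807.8 and 247.2, against a HuD mean of 107.8 and 72.9 in the input. For Shank3 they were 649.1 and 450.0, against 183.6 and 238.0. Both falls thus come mainly from signal on the IgG arrays above the input. Without IgG array 1 Dlgap2 was at −1.09 and still passed. Of 20 voltage-gated ion channel genes 5 rose and 5 fell, and over the list alone 5 rose and 3 fell (median −0.08, mean 0.10, camera's direction upward, adjusted p = 0.433). The sodium channel genes Scn1a (2.26 ± 0.27) and Scn2b (1.80 ± 0.27) and the potassium channel gene Kcnc2 (1.35 ± 0.24) rose, and Kcna2 fell (−1.54 ± 0.26). The other probe sets of Scn1a were at 0.03 and −0.34 and did not pass, nor did one of Scn2b at 0.13.

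Markers of cell types gave no list past the test. Of 11 excitatory neuron markers 3 rose and 0 fell, also over the list alone (median 0.01, adjusted p = 0.283). These were the transcription factor genes Tbr1 (2.17 ± 0.26), Bcl11b (1.40 ± 0.24) and Neurod2 (0.83 ± 0.26). Neurod2 lost its call when HuD array 1 (0.88), 2 (0.74) or 3 (0.87) or IgG array 2 (0.64) was left out, and its second probe set was at 0.42 and did not pass. For Camk2a, counted here as not past, 2 other probe sets were called lower. Of 11 interneuron markers 1 rose and 5 fell, and over the list alone 1 rose and 6 fell (median −0.71, adjusted p = 0.223). Pvalb rose (1.44 ± 0.31), while Slc32a1, the vesicular GABA transporter (−1.90 ± 0.24), Sst (−1.52 ± 0.34) and Gad1 (−1.43 ± 0.25) fell. With probe sets averaged, Slc32a1 was at −0.36 and did not pass. Without IgG array 2 Sst was at −0.92 and still passed, and a second probe set of Gad1 at −0.18 did not pass.

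Of 13 oligodendrocyte markers 0 rose and 7 fell, also over the list alone (median −0.65, adjusted p = 0.207). Sox10 (−1.44 ± 0.25), Mag (−1.07 ± 0.31), Mal (−0.98 ± 0.25) and Mobp (−0.95 ± 0.29) fell. With 75th percentile centring Mag (−0.75), Mal (−0.66) and Mobp (−0.63) did not pass, a second probe set of Sox10 was at 0.01, and one of Mobp was at −0.49, neither past the threshold. Mag also lost its call without IgG array 1 (−0.59), and Mobp without HuD array 2 (−0.78), HuD array 3 (−0.885) or IgG array 2 (−0.74). Of 13 astrocyte markers 2 rose and 6 fell, also over the list alone (median −0.18, adjusted p = 0.621). Aldoc (−1.61 ± 0.23), Ndrg2 (−1.60 ± 0.43), Gfap (−1.37 ± 0.27) and S100b (−1.31 ± 0.32) fell and Sox9 rose (1.14). Ndrg2 was at −0.78 without IgG array 1 and did not pass. The other 2 probe sets of Gfap, at −0.39 and −0.50, did not pass, and without IgG array 2 S100b was at −0.78 and still passed.

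Of 7 microglia markers 0 rose and 5 fell, also over the list alone (median −1.10, adjusted p = 0.104). C1qa (−1.50 ± 0.31), Csf1r (−1.14 ± 0.28), C1qb (−1.11 ± 0.35) and Tyrobp (−1.10 ± 0.43) fell. Tyrobp did not pass under the other 3 scalings (−0.79 with 75th percentile centring) or without HuD array 1 (−1.05), HuD array 2 (−0.97) or IgG array 2 (−0.25), and C1qb did not with 75th percentile centring (−0.79) or without HuD array 1 (−0.89) or IgG array 2 (−0.59). Without IgG array 1 the microglia list passed the list test. Of 3 endothelial markers Cldn5 fell (−1.25 ± 0.26), while Abcb1a (−0.68) and Slco1a4 (−0.50) did not pass. Over the list alone 2 fell, and the list's adjusted p was 0.318. Abcb1a passed without HuD array 3 (−0.90), and Slco1a4 was at −1.21 without IgG array 1, where it passed, and at 0.21 without IgG array 2. Of 3 choroid plexus and blood markers 0 passed, also over the list alone, with Ttr at −0.32, Kcnj13 at −0.44 and Clic6 at 0.36 (adjusted p = 0.991). Ttr passed with probe sets averaged (−0.76) and in the replicate block of 2 pairs (−0.39), and one of its other probe sets was called lower (−1.49).

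**Figure D2:**
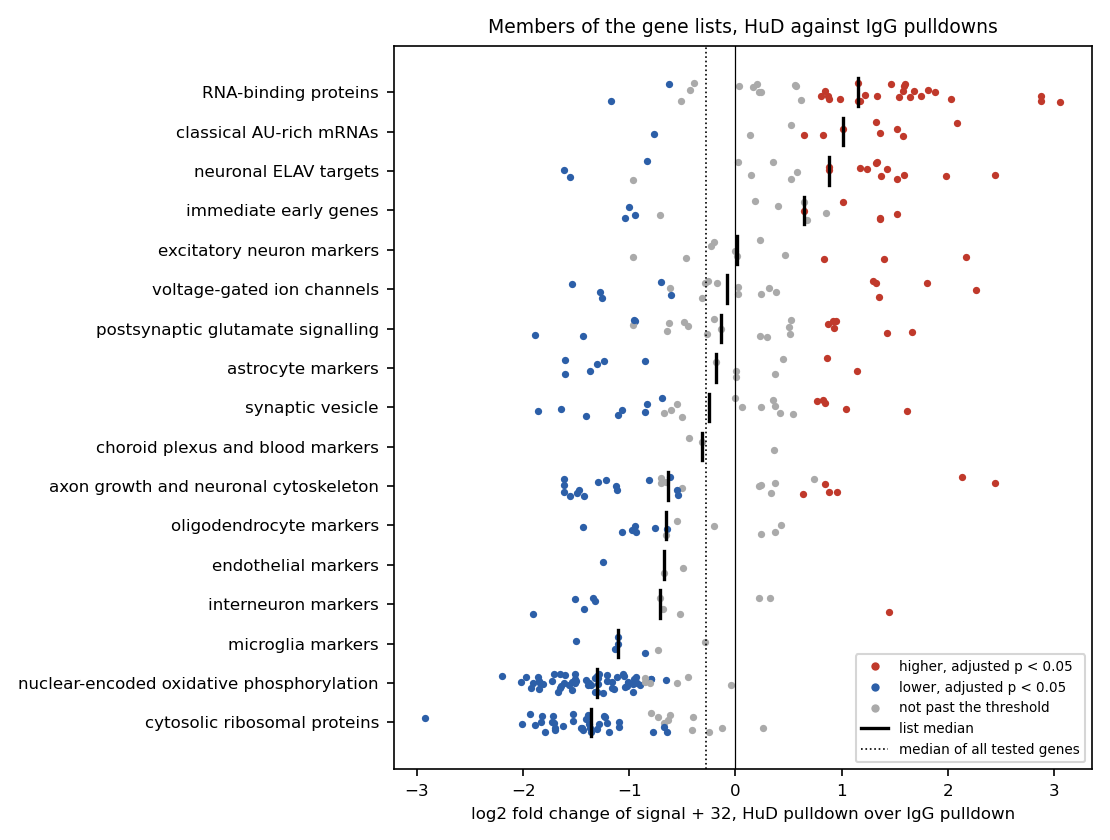
Log2 fold changes of signal + 32 between HuD and IgG pulldowns for the members of the 17 tested gene lists. Points are genes, coloured red where higher and blue where lower with adjusted p under 0.05 and grey otherwise, black ticks are list medians, and the dotted line marks the median of all tested genes (−0.28). RNA-binding protein genes centre on 1.15 and cytosolic ribosomal protein genes on −1.37.

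Over all genes 5051 of 9097 passed the threshold between HuD and IgG pulldowns, 1958 higher and 3093 lower in the HuD pulldowns. At least 4-fold differences were found for 236 of the higher and 42 of the lower genes. The 2 groups did not overlap in 70.6% of genes, against 20% by chance. The median log2 fold change of all genes was −0.28 as deposited, −0.12 after quantile normalization, −0.13 after median centring and 0.04 after 75th percentile centring, so the split moved with the scaling. Genes called higher were 38.8% of the calls as deposited, 48.3% after quantile normalization (2129 higher, 2280 lower), 48.4% after median centring (2220 higher, 2369 lower) and 59.8% after 75th percentile centring (2536 higher, 1702 lower). Under all 4 scalings 1852 genes were called higher and 1687 lower, and 1 gene was called in opposite directions. With the probe sets of a gene averaged, 33.3% of the calls were higher (1493 higher, 2994 lower).

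The sample titles carried 2 suffixes, le1 and e1_le1, that could mark processing batches, and each held HuD and IgG arrays. The HuD to IgG differences within the 2 suffixes correlated across genes (Pearson r = 0.797, Spearman rho = 0.792), and 83.8% of all tested genes had the same sign in both. With the suffix as a block 4835 genes passed. Without HuD array 1 the count of lower genes was 1982. Of 4914 genes with more than 1 tested probe set, 3211 had a called one and 144 of these were called in both directions.

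**Figure D3:**
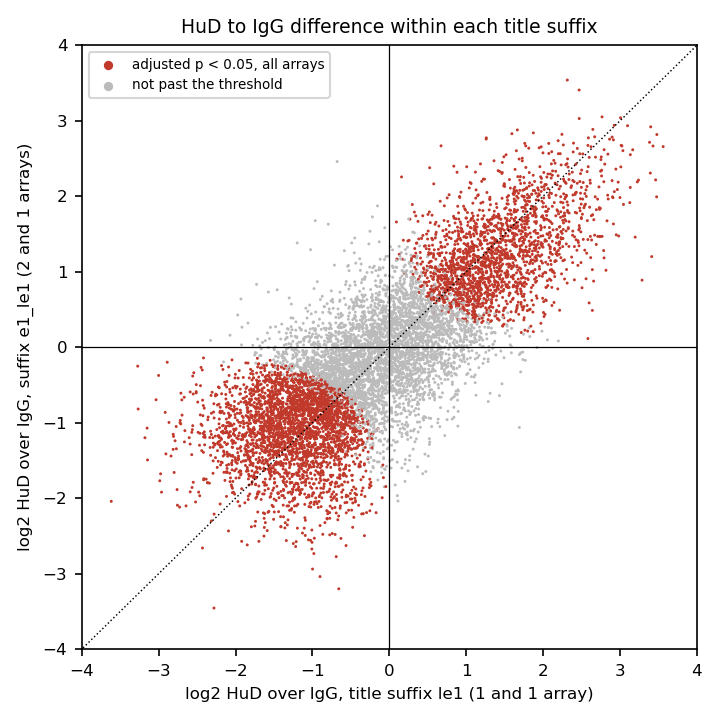
Log2 differences between HuD and IgG pulldowns within the title suffix le1 (x axis, 1 HuD and 1 IgG array) and within e1_le1 (y axis, mean of 2 HuD arrays minus 1 IgG array), 1 point per tested gene. Genes past the threshold over all arrays are red and the rest grey, and the correlation across genes was 0.797.

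The comparison of HuD pulldowns with the input asked which RNAs were enriched over their share of total RNA. Fbxo3 was 10.3-fold higher in the HuD pulldowns than in the input (log2 fold change 3.36 ± 0.34), Kantr 10.1-fold (3.34 ± 0.39), Sec22b 9.57-fold (3.26 ± 0.33) and Tial1 9.21-fold (3.20 ± 0.36). Dck, the deoxycytidine kinase gene, was 8.20-fold higher, Klhl15 8.14-fold, the adhesion molecule gene Alcam 8.08-fold, Hsd17b7 7.79-fold, the BMP pathway gene Smad1 7.78-fold and Csrnp2 7.74-fold. Among the falls, the apolipoprotein gene Apoe was 6.77-fold lower (−2.76 ± 0.65), Pla2g7 6.62-fold (−2.73 ± 0.33) and the proteasome gene Psmb7 6.31-fold (−2.66 ± 0.37). Cuedc2 was 6.30-fold lower, Pld3 6.29-fold, the proton pump gene Atp6v0a1 5.82-fold, Itih3 5.51-fold, the glycolytic gene Pfkl 5.45-fold and the spermidine synthase gene Srm 5.42-fold. The adjusted p was at most 0.00143 for the rises and 0.00831 for the falls. Kcnip3, a calcium-binding partner of potassium channels, also fell, from a signal of 355 in the input to 10.4 ± 3.6 (SD, n = 3), which is below the array medians, so the size of its fall is set by the pseudocount (−3.19 with 32). With probe sets averaged, Tial1 was at 0.71 and did not pass. Between HuD and IgG pulldowns, second probe sets of Cuedc2 (−0.36), Atp6v0a1 (0.01) and Kcnip3 (−0.18) did not pass, while that of Pfkl was called lower (−1.01).

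In the gene lists 21 of the 37 RNA-binding protein genes were higher than in the input and 0 lower (median 1.29), and 9 of 21 neuronal ELAV targets were higher and 3 lower (median 0.70). Of the ribosomal protein genes 0 were higher and 20 lower (median −1.003), and of the oxidative phosphorylation genes 0 were higher and 25 lower (median −0.92). Between IgG pulldowns and input these lists of ribosomal and oxidative phosphorylation genes had medians of 0.44 and 0.395. Their level on the IgG arrays thus adds to their difference between HuD and IgG pulldowns. Over all genes 3783 passed the threshold, 1428 higher and 2355 lower, with a median log2 fold change of −0.32. The share called higher was 37.7% as deposited, 48.8% after quantile normalization, 33.0% after median centring and 65.3% after 75th percentile centring (1963 higher, 1041 lower), and the median of all genes was −0.12, −0.385 and 0.04 under these 3 scalings. Under all 4 scalings 1207 genes were called higher and 1013 lower, and 1 in opposite directions. The input was 1 array, assumed to vary like the pulldowns, and without HuD array 1 the counts were 927 higher and 1160 lower.

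Both comparisons use the same HuD arrays. Called higher in both were 1287 genes and lower in both 1994, while 4 were called in opposite directions. Independent lists of these sizes would share 307 and 801, but these figures ignore the shared HuD arrays. The 20 simulations with no effect shared 0. Such simulations call few or no genes, so their 0 gives no level for chance. The log2 fold changes of the 2 comparisons correlated across genes with r = 0.898 and a covariance of 0.922, where simulations gave 0.316 and 0.032. The simulations carry the shared HuD arrays, so 0.032 is what independent noise of those arrays adds to the covariance. This argues against such noise as the main source of the 0.922. A deviation common to all 3 HuD arrays was not simulated and stays open, and the group could not be split into parts of at least 2.

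The comparison of IgG pulldowns with the input asked what the beads and IgG alone enriched. Mid1, a ubiquitin ligase gene, was 6.52-fold higher in the IgG pulldowns (log2 fold change 2.70 ± 0.36, adjusted p = 0.0478) and the noncoding RNA Meg3 was 5.25-fold higher (2.39 ± 0.30, adjusted p = 0.0478). These were the 2 genes past the threshold, against 641 at an unadjusted p under 0.05, and 0 genes were called lower. Both calls were lost with median centring (2.485 and 2.17), with 75th percentile centring (2.74 and 2.43), with a pseudocount of 100 (2.10 and 2.32), and with probe sets averaged, where Mid1 was at 0.86 and Meg3 at 2.03. They were also lost with no filter, without a variance trend, with the title suffix as a block (2.73 and 2.38), and without HuD array 1, HuD array 2 or IgG array 1. Without IgG array 2, 1 IgG array is compared with 1 input array, and the spread comes from the HuD arrays alone. Not past the threshold were Daam1 (2.46 ± 0.39), Zbtb20 (2.23 ± 0.42), the noncoding RNA Miat (2.08 ± 0.34) and the complement gene Cfp (2.02 ± 0.31), whose input signal of 24.0 lies near the array median. Without IgG array 2 these 4 were at 2.845, 2.53, 2.32 and 1.99. Of the genes with negative differences, those with the lowest unadjusted p were Ncan (−1.73 ± 0.33), Elmo1 (−1.65 ± 0.33), Pla2g7 (−1.54 ± 0.35), Pdzd11 (−1.51 ± 0.35), Cnnm4 (−1.33 ± 0.34) and Kcnip3 (−1.28 ± 0.31), none past the threshold. The comparison rests on 2 IgG arrays and 1 input array.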

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

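Of the tests in this part, those on starting RNA, 3′ bias, the title suffix and array scaling were chosen after their results were seen, and the test with lists matched on input signal was written before its result was seen.

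Control probe sets outside the comparisons drew attention because they were above their level in the input. The 4 poly-A controls, spiked into RNA before labelling, lay 3.96 higher on the log2 scale in the mean of the IgG arrays than in the input. Their signal was 25.1 and 9.60 times that of the input on IgG arrays 1 and 2, and 1.93, 5.89 and 1.89 times on HuD arrays 1, 2 and 3. Relative to the hybridisation controls of each array these ratios were 10.26 and 3.18, and 1.14, 1.97 and 1.07. Probe sets without a single gene symbol also carried signal, and 297 of the 2802 tested were higher in the HuD than in the IgG pulldowns, 37 of them at least 4-fold, while 765 were lower.

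Many genes differed between HuD and IgG pulldowns. If a difference in the amount of starting RNA were the cause, the IgG arrays, whose poly-A controls lie furthest from the input's, should differ most from the input, but every HuD array differed from it at least 2-fold in 3359 or more genes and no IgG array in more than 764. For 3′ bias, the ratios of 3′ to 5′ control probe sets of Actb and Gapdh were compared. The ratios ranged over 2.49 and 0.66 (log2) within the HuD arrays and differed by 0.84 and 0.11 between the groups. Yet HuD arrays differed from each other in at most 322 genes and from IgG arrays in at least 3155. The ratios cover only Actb and Gapdh, so 3′ bias of other transcripts was not measured. A batch marked by the title suffix is argued against by the 4835 genes past the threshold with the suffix as a block and the correlation of 0.797 within suffixes. Binding of RNA by HuD, the difference the design names, may account for the pattern, but binding by the anti-myc antibody or its beads without HuD stays open, because a pulldown with that antibody from animals without the transgene was not analysed here.

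Genes of the ribosome and of oxidative phosphorylation were lower in the HuD pulldowns. If their high signal in the input were the cause, lists of genes with like input signal should have medians as low, but 0 of 10000 matched lists did for either list, and the matched lists centred on −0.39 and −0.34 against −1.37 and −1.30. Array scaling moved the medians without bringing them to 0. The least negative of both lists under 4 scalings was −0.99 with a typical standard error of 0.34. All 4 scalings bring the arrays to a common overall level, so these values show only a smaller share of the signal. They cannot decide whether less of these RNAs was recovered in total, and the higher poly-A controls on the IgG arrays leave a difference in total RNA open. A candidate biological explanation is that these mRNAs, if they are short and have few AU-rich stretches, are poorly bound by HuD. Transcript lengths and sequences were not used here, so neither binding sites nor an effect of length on the pulldown or the labelling was tested. The lists' calls are also lost with an estimated correlation, so a shared shift of these genes between 2 small groups stays open.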

How the results depend on the processing

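Most named genes kept their direction and their side of the threshold. For HuD against IgG 1678 of the repeated estimates did, 57 lost a call, 14 gained one and 9 changed sign. For HuD against input 314 did and 1 lost a call, and for IgG against input 156 did, 20 lost a call and 7 gained one. The changes of sign were in genes not past the threshold: App at −0.06 with probe sets averaged, and Kcna1 at −0.175 with quantile normalization and 0 in the replicate block of 2 pairs. With 1 array left out App ranged from −0.038 to 0.336, Cplx2 from −0.139 to 0.851, Kcna1 from −0.292 to 0.345 and Slco1a4 from −1.209 to 0.213. The cause was not tested. For HuD against IgG the counts that moved over 1.5 times were 1702 lower genes with 75th percentile centring, 2814 genes (1328 lower) above the 75th percentile of mean signal, where fewer genes were tested, and 9170 calls (3309 higher, 5861 lower) with every probe set tested. Leaving out 1 array gave 3470 to 4834 genes, 1488 to 1926 higher and 1982 to 2908 lower, the lowest counts without HuD array 1. For HuD against input they were 1041 lower genes with 75th percentile centring, 2490 genes (1453 lower) with no filter, 2173 (1013 lower) above the 75th percentile, 5711 (2196 higher) with every probe set, and 929 higher with probe sets averaged. Leaving out 1 array gave 2087 to 4814 genes, 927 to 1779 higher and 1160 to 3036 lower, the lowest counts without HuD array 1. For IgG against input 0 genes passed with median or 75th percentile centring, a pseudocount of 100, no filter, probe sets averaged, no variance trend, and the suffix block, against 551 to 993 at an unadjusted p under 0.05, and 54 probe sets (53 higher, 1 lower) with every probe set. Leaving out 1 HuD array gave 0 to 2 genes, all higher. Of the lists, 5 passed with the preset correlation, 0 with an estimated one and 10 with fry, which does not compare a list with other genes. Of the repeated list results 193 kept their call, 5 lost it and 6 gained it. Within a suffix the titles number 2 pairs of HuD and IgG arrays alike. Deviations of these arrays from their group means correlated at −0.03 and 0.395. Those of HuD array 2 and IgG array 1, which carry a like number in their titles but different suffixes, correlated at 0.337. Deviations within a group cancel out, so 0.337 follows largely from the other values. These correlations therefore cannot decide whether arrays were paired. The 2 pairs also share a title suffix, and whether they were prepared together is not known here. The replicate block of these 2 pairs gave 5411 genes for HuD against IgG, and the suffix block gave 4835 for HuD against IgG and 2853 for HuD against input. The block of pairs holds no input array and was not run for the input comparisons. Signal over background limits dim genes, for which no detection call was at hand.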

Other observations

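The family scan was chosen after the data were seen. The tests on pairs of probe sets were written before their results were seen.

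Genes of the mitochondrial ribosome and of the proteasome were lower in the HuD pulldowns, and Ube genes, of ubiquitin conjugation or ligation, were higher. Among 119 groups of at least 12 genes that share the first 3 letters of their symbols, 7 passed camera with the preset correlation and 0 with an estimated one (adjusted p = 0.934 for each of the 7). Of 73 mitochondrial ribosomal protein genes 53 fell and 4 rose (median log2 fold change −1.14, camera, adjusted p = 3.28e-05), with Mrpl11 at −2.22 ± 0.29 and Mrps26 at −1.92 ± 0.26, while Mrpl1 (2.61 ± 0.32) and Mrpl35 (2.52 ± 0.29) rose. Of 44 genes named for the proteasome 35 fell and 4 rose (median −1.14, adjusted p = 0.000518), with Psmd13 at −1.93 ± 0.37 and Psmc3 at −1.77 ± 0.30, while Psmd11 rose (1.96 ± 0.25). Of 30 Ube genes 17 rose and 1, a pseudogene, fell (median 1.12, camera, adjusted p = 0.00126). The conjugation genes Ube2g1 and Ube2v2 were at 2.69 ± 0.28 and 2.22 ± 0.25, and the ligase gene of Angelman syndrome, Ube3a, at 1.19 ± 0.23. Second probe sets of Mrpl35 and Ube2v2 were at −0.191 and −0.115. Of 20 protocadherin genes 7 rose and 0 fell (median 0.48, adjusted p = 0.0148), but their related sequences can share probes. The other groups past the test, Ndu, Rpl and Rps, overlap the lists of oxidative phosphorylation and ribosomal genes. The counts moved with the scaling. With 75th percentile centring 34 mitochondrial ribosomal genes fell and 6 rose, and 23 proteasome genes fell and 4 rose. Under that scaling 17 Ube genes rose and 1 fell, and 12 protocadherin genes rose and 0 fell. The medians were then −0.82 for both the mitochondrial ribosome and the proteasome, 1.44 for Ube genes and 0.79 for protocadherins, so no direction turned.

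Genes singled out after their values were seen showed opposite changes of 2 probe sets on the same arrays. One probe set of Actb was at a log2 fold change of 1.61 and another at −3.22 between HuD and IgG pulldowns. For Map4, a microtubule-associated protein gene, the values were 2.05 and −1.07, for Eif1ax 1.99 and −1.18, for Wtap 1.64 and −1.06, and for Prkar1a 1.55 and −1.35. The difference between 2 probe sets of a gene does not depend on the scaling of an array except through the pseudocount. Of 4914 genes, the difference between the 2 brightest tested probe sets passed the threshold between HuD and IgG pulldowns for 829, or 16.9%, of which 791 differed at least 2-fold.

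Signals near background do not account for the pattern alone, since 14.6% of the 1557 pairs with both probe sets bright passed as well. Probe sets of the types _x_at and _s_at do not either, since 19.7% of the 3280 pairs without them passed. Related transcripts can also bind probe sets of other types, so binding of other transcripts stays open. As a hypothesis, transcripts of 1 gene with different 3′ ends may differ in their binding to HuD, and a probe set in a distal 3′ untranslated region or in unspliced RNA would then move apart from one in the shared part. Probe positions were not used here, so this was not tested, and wrongly assigned probe sets stay open too. Unlike 3′ bias of the arrays was not tested for these pairs either and stays open. The 3′ to 5′ control ratio of Actb, 1 of the genes above, was 15.4, 5.6 and 31.2 on HuD arrays 1, 2 and 3. On IgG arrays 1 and 2 it was 17.9 and 34.4.

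Ncan and Elmo1 had log2 differences of −1.73 and −1.65 between IgG pulldowns and input, not past the threshold, and were higher in the HuD than in the IgG pulldowns (log2 fold change 2.34 and 2.28), where their HuD signals were 1151.6 ± 79.0 and 1436.2 ± 127.1 (SD, n = 3) against inputs of 744.3 and 912.6. Other probe sets of Ncan were at 0.06 and 0.81 between the pulldowns. The 18S ribosomal RNA control probe set had signals of 883, 930 and 420 on the HuD arrays, 6609 and 2945 on the IgG arrays and 2644 on the input.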
